A study of Mus musculus with 2 samples.

How the data were processed

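Ventral prostate RNA of AR-E231G and AR-T857A transgenic mice was profiled on Affymetrix Mouse Genome 430 2.0 arrays, with 1 array per line and the RNA of 3 mice pooled on each. Per the labels and the series' design text, RNA was extracted with the RNeasy kit, 10 µg was hybridised, and labelling followed the manufacturer's standard protocol. The authors deposited 1 value per probe set after Robust Multiarray Averaging (RMA), which corrects background, equalises the distributions of the arrays and summarises the probes of a set. The software, its version and which arrays were normalised together are not given in the sources used here. The log base is not stated for the deposited values and was taken as log2 from their range. The distributions differed by at most 0.155 at any quantile examined, and Pearson's r between the arrays was 0.982 across probe sets, which are not independent replicates.

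The table held 45101 probe sets. The 64 control probe sets were set aside, leaving 45037. The platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160, and genes were named only from probe sets with 1 symbol. Of those, 34741 matched the RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other, and 0 symbols changed. Because the array files name no build, no coordinates are given. A symbol is that of the annotation, and genes without a probe set of their own there, Ar among them, were not analysed here.

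Probe sets whose mean over both arrays reached the 40th percentile (4.98) were kept, leaving 27022 probe sets and 13329 of 18194 genes. Each gene was represented by its brightest probe set with 1 symbol, and 6049 genes had at least 2 probe sets past the filter. With 1 array per line no test was possible, so no p-value, standard error or SD between samples is given. The difference was the value on the AR-E231G array minus that on the AR-T857A array, a fold is 2 raised to its size, and genes were called by size alone at 1.5 log2 units. The authors' design text names a cut-off of 1.5 that was read on the log scale, and a fold of 1.5 was tried as the other reading. Folds of RMA values tend to be compressed at low intensity.

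For 34 gene lists with 524 entries, of which 0 were unmatched and 3 were matched by an older symbol, the median difference of the measured members was computed. It was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins (seed 1). The percentile describes these arrays and is not a p-value. The lists, the threshold, the filter, the alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names Ar and Pbsn, up to 15 genes past the threshold with the highest and up to 15 with the lowest difference, and from each list up to 4 members with the largest differences and members needed to say which go against their list. A gene outside the rule is said to be chosen after its values were seen.

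Alternatives were thresholds of 1 log2 unit and of 1.5-fold, no intensity filter, a filter at the 60th percentile, removal of a loess trend (span 0.4) of the difference on the mean, centring of the median difference, the mean over all probe sets of a gene, and leaving out probe sets ending in _s_at, _x_at or _a_at. For the lists, the mean of the members and the list without its largest member were also used. A filter on the brighter of the 2 arrays was added after the data had been seen.

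The procedure was tested on simulated data for this comparison. The noise was drawn from a normal distribution with the robust spread of these same differences per intensity bin. It held no heavier tails and no separate spread between animals. The simulated calls therefore give no rate of false calls among the real genes. Of 50 simulated genes per size among 13329, those with a true log2 difference of 1 were called in 2%, of 2 in 98% and of 3 or 5 in 100%, and 6 of 13129 unchanged genes were called. Simulated lists of 15 members shifted by 0.15 lay at or above the 95th percentile in 63.3% of 60 draws, those shifted by 0.3 in 98.3% and unshifted ones in 8.33%. Their members were drawn at random with independent noise. These shares therefore give no rate for real lists, whose genes can vary together. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.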

Results

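Gene expression was measured in the ventral prostate of 12-week-old male mice of 2 transgenic lines on the FVB/N background. Both lines carry a mutated androgen receptor (AR) under the probasin (Pbsn) promoter, which is active in prostate epithelium. The substitution of AR-E231G lies in the amino-terminal domain and that of AR-T857A in the ligand-binding domain. Each line was represented by 1 array, hybridised with the pooled RNA of 3 mice, so there was no replicate and no difference below could be set against a spread between animals. The probe-set values ranged from 1.79 to 14.8 on the AR-E231G array and from 1.82 to 14.6 on the AR-T857A array, with medians of 5.56 and 5.58. The number of arrays limits the precision of every value.

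The comparison of both lines addressed how the ventral prostate transcriptome of the AR-E231G line, known as a line that develops prostate cancer with age, differed at 12 weeks from that of the AR-T857A line. The differences are log2 values on the AR-E231G array minus those on the AR-T857A array. Of 10 genes of the Klk1b family of kallikreins, secreted serine proteases encoded by a cluster of close paralogs, 7 passed the size threshold, all higher on the AR-E231G array. Klk1b27 measured 12.05 against 4.12, a difference of 7.93 or 243-fold. Klk1b16 measured 10.95 against 4.19, a difference of 6.77 or 109-fold. The AR-T857A values of Klk1b27 and Klk1b16 lay below the filter intensity, so the exact folds depend on the background level. Klk1b21 and Klk1b24 were 41.8-fold and 32.1-fold higher, with differences of 5.38 and 5.0. Bpifb3, a member of the family of BPI-fold secreted proteins, differed in the other direction, with 5.53 against 10.42, a difference of -4.89 or 29.7-fold. Its AR-E231G value lay near the median of that array (5.56), so this fold may depend on the background level too. Bpifb3 and each Klk1b gene named in this paragraph rested on 1 probe set past the filter.

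Of 13329 genes past the intensity filter, 31 were at least 1.5 log2 units (2.83-fold) higher on the AR-E231G array and 13 were lower by that size, together 0.330%. Counted as probe sets, 58 were higher and 41 lower. The 5 genes above differed by more than 4 in size, and the next difference was 2.85. The Klk1b family made up 7 of the 31 higher genes, counting Egfbp2, the kallikrein that binds epidermal growth factor. Egfbp2 was 7.21-fold higher (2.85), Klk1b11 4.62-fold (2.21) and Klk1b5 4.09-fold (2.03), and the second probe set of Klk1b5 gave 3.04. Klk1b1 and Klk1b8 did not pass the threshold, with differences of 0.89 and 0.13, and Klk1b7-ps, a pseudogene below the intensity filter, by -1.08. Klk1, the tissue kallikrein of the same cluster, differed by -0.04 on its brightest probe set, with -0.02 to 0.89 on 3 dimmer ones. Because these paralogs are nearly identical in sequence, part of a signal may belong to another member, and the probe sets of Egfbp2, the second one of Klk1b5 and the brightest one of Klk1 are of a type shared between transcripts.

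**Figure D1:**
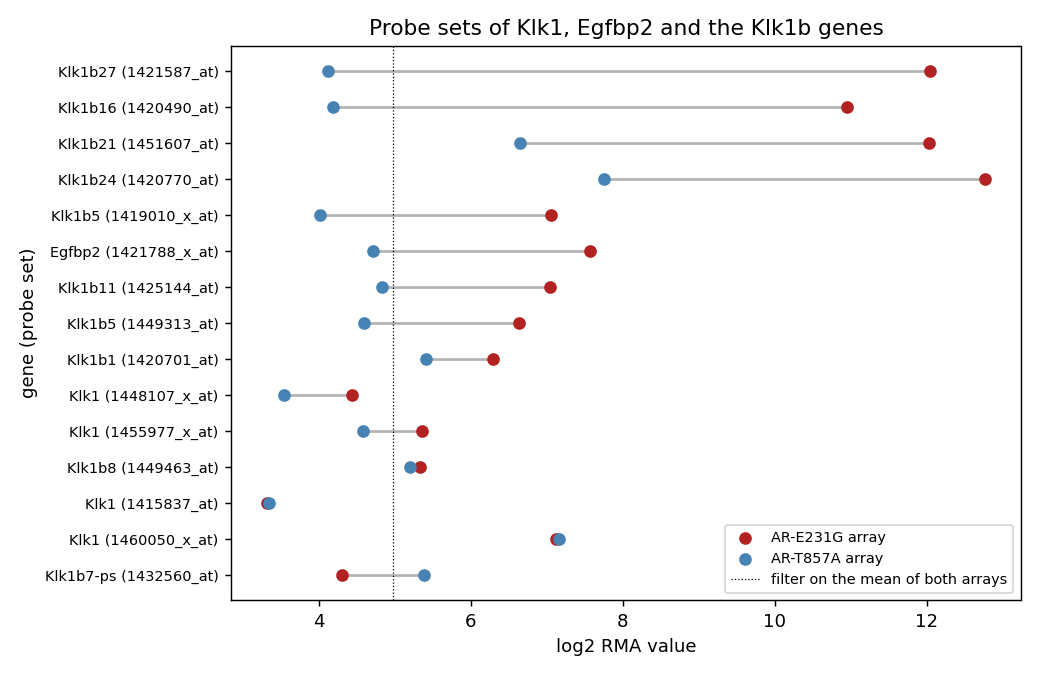
Log2 RMA values of the single-gene probe sets of the Klk1b family and Klk1 on the AR-E231G and AR-T857A arrays, 1 array of pooled RNA per line, so no error bars are drawn, with the intensity filter on the mean of both arrays as a dotted line. Klk1b27, Klk1b16, Klk1b21 and Klk1b24 differed by 5.0 to 7.93, whereas the brightest probe set of Klk1, of a type shared between transcripts, differed by -0.04.

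The other 8 of the 15 genes with the highest differences had different known functions. Cited1, a transcriptional co-regulator that binds CBP/p300, was 6.69-fold higher on the AR-E231G array (2.74). Cyp2e1, a cytochrome P450 that oxidises ethanol and other small molecules, was 6.42-fold higher (2.68). Xkr5, of the XK-related membrane protein family, was 6.0-fold higher (2.59), and Rhox9, a homeobox gene of the reproductive Rhox cluster, 5.41-fold (2.44). Greb1, a nuclear receptor cofactor known as a target of estrogen and androgen receptors, was 5.72-fold higher (2.52), but its other probe set differed by 0.48. Fut4, a fucosyltransferase that makes Lewis x antigens, differed by 2.07, and its other probe set by 1.45. Ampd3, which deaminates AMP, was 4.10-fold higher (2.03). Ptgds, the lipocalin-type prostaglandin D synthase, was 3.82-fold higher (1.93), with 2.76 for its other probe set. The AR-T857A values of Klk1b27, Klk1b16, Egfbp2, Xkr5, Greb1, Rhox9, Klk1b11 and Klk1b5 lay below the filter intensity of 4.98, where a fold depends on the background level.

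After Bpifb3, the lower genes were all within -1.51 to -1.84. Smim38, which encodes a small membrane protein, differed by -1.84, but its 2 other probe sets gave -1.90 and 0.65. Prkar2b, a regulatory subunit of protein kinase A, differed by -1.78 against 0.03 and -0.76 for its other probe sets. Map3k10, a kinase of the JNK pathway, differed by -1.67 while its 3 other probe sets lay between -0.03 and 0.23. Vangl2, a core component of planar cell polarity, differed by -1.67 and -0.78. Capn13, a calpain protease, and Gckr, the glucokinase regulator, were 3.15-fold and 3.14-fold lower on the AR-E231G array. Rhox6, a homeobox gene of the same cluster as Rhox9, differed by -1.64, opposite to Rhox9. Zfp418 (-1.66), Cyp2c54 (-1.57), Slc4a8, a bicarbonate transporter (-1.53), and Pcgf2, a Polycomb group protein (-1.51), completed the group with Ndrg4, whose probe sets gave -1.57 and 0.32. The AR-E231G values of Vangl2, Zfp418, Gckr, Cyp2c54, Slc4a8 and Ndrg4 lay below the filter intensity, so these differences depend on the background level too.

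**Figure D2:**
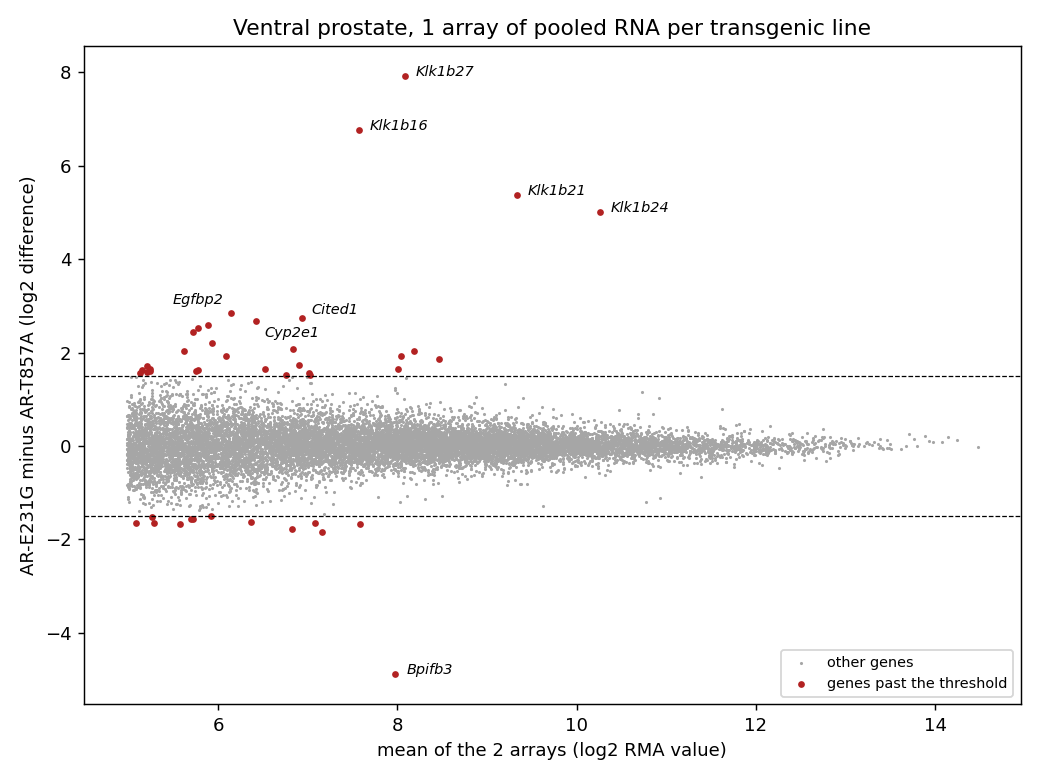
Log2 difference (AR-E231G minus AR-T857A, 1 array each) against the mean log2 RMA value of both arrays, 1 point per gene past the intensity filter, with red points for the 44 genes past the threshold and dashed lines at 1.5 in either direction. Klk1b27, Klk1b16, Klk1b21, Klk1b24 and Bpifb3 stand apart from the other genes.

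Pbsn, a secretory protein gene, measured 13.83 on the AR-E231G array and 13.69 on the AR-T857A array (0.14). A probasin promoter drives both transgenes, but the Pbsn value does not measure them. The Ar transcript itself was not analysed here, so whether transgene levels differed between the lines is not known. Among 28 measured androgen-responsive genes, 19 were higher and 9 lower on the AR-E231G array, with a median difference of 0.14. That median lay at percentile 99.9 among 10000 random lists matched on mean expression, and at percentile 92.0 when the mean of the members was used. None of them passed the threshold. Zbtb16 (0.58), Homer2 (0.48) and Pias1 (0.45) were highest, although over all their probe sets Zbtb16 averaged 0.08 and Pias1 -0.13. The ubiquitin ligase gene Herc3 differed by -1.05. The prostate secretory proteins were divided, 6 higher and 7 lower of 13 (median -0.03, percentile 28.7), with Tgm4, the prostate transglutaminase, at 0.56 and Apof at -0.44.

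The medians of the epithelial lists lay between the 5th and the 95th percentile of random lists in the main setting. Luminal markers were 8 higher and 8 lower (median 0.02, percentile 60.1), with the tight junction gene Cldn3 at 0.43 and the stem cell marker Prom1 at -0.25. Basal markers were 6 higher and 6 lower (median 0.00, percentile 40.4), with Aqp3 at 0.38 and Perp at -0.32, but their median was -0.18, at percentile 2.25, without probe sets shared between transcripts. Of 12 proximal luminal progenitor markers 7 were higher (median 0.10, percentile 91.8), among them Atp10b (0.77), Lcn2 (0.62) and the keratin Krt4 (0.44). Of 7 neuroendocrine markers 4 were higher (median 0.11, percentile 72.9, but a median of -0.047 without the intensity filter), with the forkhead factor Foxa2 at -0.82.

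Fibroblast, matrix and smooth muscle genes lay higher on the AR-E231G array by small amounts. All 17 measured fibroblast and matrix genes were higher, with a median of 0.26, and none of the 10000 matched lists reached that value (percentile 100). Thy1 differed by 0.55, the matricellular gene Postn by 0.43, the collagen gene Col5a2 by 0.42 and the proteoglycan gene Bgn by 0.36, and none passed the threshold. Of 15 smooth muscle markers 13 were higher (median 0.11, percentile 99.0, but 94.8 over all probe sets), led by Synpo2 (0.62, or 0.09 over all its probe sets) and Lmod1 (0.49). The 14 endothelial markers were 8 higher and 6 lower (median 0.07, percentile 65.7), with Vwf, the von Willebrand factor, at 0.61 and the VEGF receptor Kdr at -0.38. Of 5 nerve and Schwann cell genes 4 were higher (median 0.13, percentile 77.1), with the adhesion molecule gene Ncam1 at 0.34 and the myelin gene Pmp22 at -0.45.

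Genes of immune cells and of inflammation were also compared. All 5 measured B and plasma cell markers were higher on the AR-E231G array (median 0.51, percentile 98.4, but 90.1 and a median of 0.23 without the intensity filter). Jchain, the joining chain of secreted immunoglobulins, was 3.04-fold higher (1.60) and passed the threshold, although its AR-T857A value of 4.96 lay just below the filter intensity. Igha, the heavy chain of immunoglobulin A, differed by 1.13. Of 10 acute phase and complement genes 8 were higher (median 0.38, percentile 99.99), none past the threshold. Among them were the serum amyloid genes Saa1 (1.32) and Saa3 (0.69), complement factor B, Cfb (0.86), and the iron-siderophore binding lipocalin Lcn2 (0.62). Antigen presentation genes were 11 higher and 2 lower (median 0.10, percentile 88.2), except that Tap1, the peptide transporter of that pathway, stood at -1.46. Myeloid markers were 11 higher and 4 lower (median 0.11, percentile 87.1), with Laptm5 at 0.76, or 0.22 over all its probe sets, and the leukocyte marker Ptprc at -0.62. Of 5 T and NK cell markers 4 were higher (median 0.14, percentile 72.7), with Nkg7 at 0.81 and Cd8a at -0.52. Interferon-stimulated genes were 6 higher and 9 lower (median -0.14, percentile 5.81), with the guanylate-binding protein gene Gbp2 at -0.60, or -0.16 over all its probe sets, and Rtp4 at 0.50.

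Genes of the unfolded protein response were lower as a list. Of 22 measured members 18 were lower on the AR-E231G array, with a median of -0.12 at percentile 0.06, and none passed the threshold. The stress transcription factor gene Atf3 differed by -0.66, Xbp1, a transducer of the response, by -0.40, the protein disulfide isomerase gene Pdia4 by -0.27 and the glutathione-degrading Chac1 by -0.27. Hypoxia and glycolysis genes were 6 higher and 9 lower (median -0.12, percentile 1.86), but the median was 0.14 without probe sets shared between transcripts. Their extremes were Adm, the vasodilator adrenomedullin, 3.64-fold higher (1.86) and past the threshold, and the oxygen sensor Egln3 at -1.30, or -0.44 over all its probe sets. Immediate early genes were 8 higher and 7 lower (median 0.04, percentile 66.9), with Hspa1a at 0.57 and Fos at -0.56. Of 17 glutathione and oxidative stress genes 12 were higher (median 0.08, percentile 93.7, but 0.03 over all probe sets), with the heme oxygenase Hmox1 at 0.49 and the glutathione peroxidase Gpx2 at -0.59.

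The medians of the metabolic, growth and signalling lists lay between the 5th and the 95th percentile of random lists in the main setting. Oxidative phosphorylation genes were 10 higher and 9 lower (median 0.01, percentile 60), with the complex III subunit gene Uqcrc2 at -0.39. Cholesterol and fatty acid synthesis genes were 10 higher and 9 lower (median 0.02, percentile 51.9), with the fatty acid synthase Fasn at 0.82 and the sterol regulator Srebf2 at -0.38. Polyamine metabolism genes were 3 higher and 5 lower (median -0.03, percentile 30.3), the spermine oxidase Smox being highest at 0.18. Cell cycle genes were 11 higher and 10 lower (median 0.01, percentile 49.8), with the replication helicase subunit Mcm2 at 1.41 and the centromere protein gene Cenpf at -0.66. Wnt and TGF-beta target genes were 11 higher and 5 lower (median 0.13, percentile 88.5), and their mean of 0.24 lay at percentile 98.1. Their median was 0.19 (percentile 98.8) over all probe sets and 0.22 (percentile 97.6) without probe sets shared between transcripts. The matricellular growth factor gene Ccn2 (1.16), the inhibitor of differentiation Id1 (1.02) and Tgfb3 (0.88) were the highest of them. Prostate cancer-associated genes were 7 higher and 9 lower (median -0.05, percentile 17.5), with the gelatinase Mmp9 at 0.74, or 0.32 over all its probe sets, and the Golgi protein gene Golm1 at -0.70.

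Clock genes that peak with Dbp were 7 higher and 3 lower (median 0.17, percentile 91.9), with the repressor Bhlhe41 past the threshold at 1.59 and Per2 at 0.74. Their median was 0.075 (percentile 66.3) with a filter at the 60th percentile, and their mean was 0.31 (percentile 98.9). Clock genes that peak with Bmal1 were 3 higher and 2 lower (median 0.09, percentile 66.0), Cry1 being highest at 0.28. Genes of neighbouring tissues were measured on the same arrays. The 6 adipocyte genes had a median of 0.69 at percentile 99.98, with 4 higher and 2 lower. The adipokine Adipoq (1.71) and the carbonic anhydrase Car3 (1.66) passed the threshold and the adipogenic receptor Pparg differed by 1.09, whereas Fabp4 stood at -0.26 and Lpl at -0.01. Adipoq and Pparg measured 4.35 and 4.49 on the AR-T857A array, below the filter intensity, so their differences depend on the background level. With a filter at the 60th percentile, which left 3 members, the adipocyte median was -0.01. Of 4 seminal vesicle secretory proteins 2 were higher and 2 lower (median 0.05, percentile 58.4), with Ceacam10 at 1.47 and Svs5 at -1.38. Of 10 skeletal muscle genes 7 were higher (median 0.10, percentile 77.4), with the myosin gene Myh2 at 0.55. Of 5 urothelial genes 3 were higher (median 0.05, percentile 61.8), with the uroplakin gene Upk1b at 0.35. Of 4 red blood cell genes 3 were lower (median -0.24, percentile 15.6), with Slc4a1 at -0.35. Of 3 sex-linked check genes 1 was higher and 2 lower (median -0.03, percentile 37.1), with Kdm5d at 0.72 and Uty at -0.63, or 0.10 without probe sets shared between transcripts. In all, 6 of the 34 lists lay above the 95th percentile and 2 below the 5th. By chance 3.4 would lie outside if the members of a list varied independently, as randomly drawn genes may. Genes of 1 cell type or pathway can vary together, so the excess over 3.4 cannot be read as evidence. The sign of the list value changed under at least 1 alternative for 14 lists, namely adipocyte, hypoxia, neuroendocrine, luminal, basal, cell cycle, cholesterol, oxidative phosphorylation, prostate cancer-associated, Bmal1-phase clock, seminal vesicle, skeletal muscle, urothelial and sex-linked genes.

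**Figure D3:**
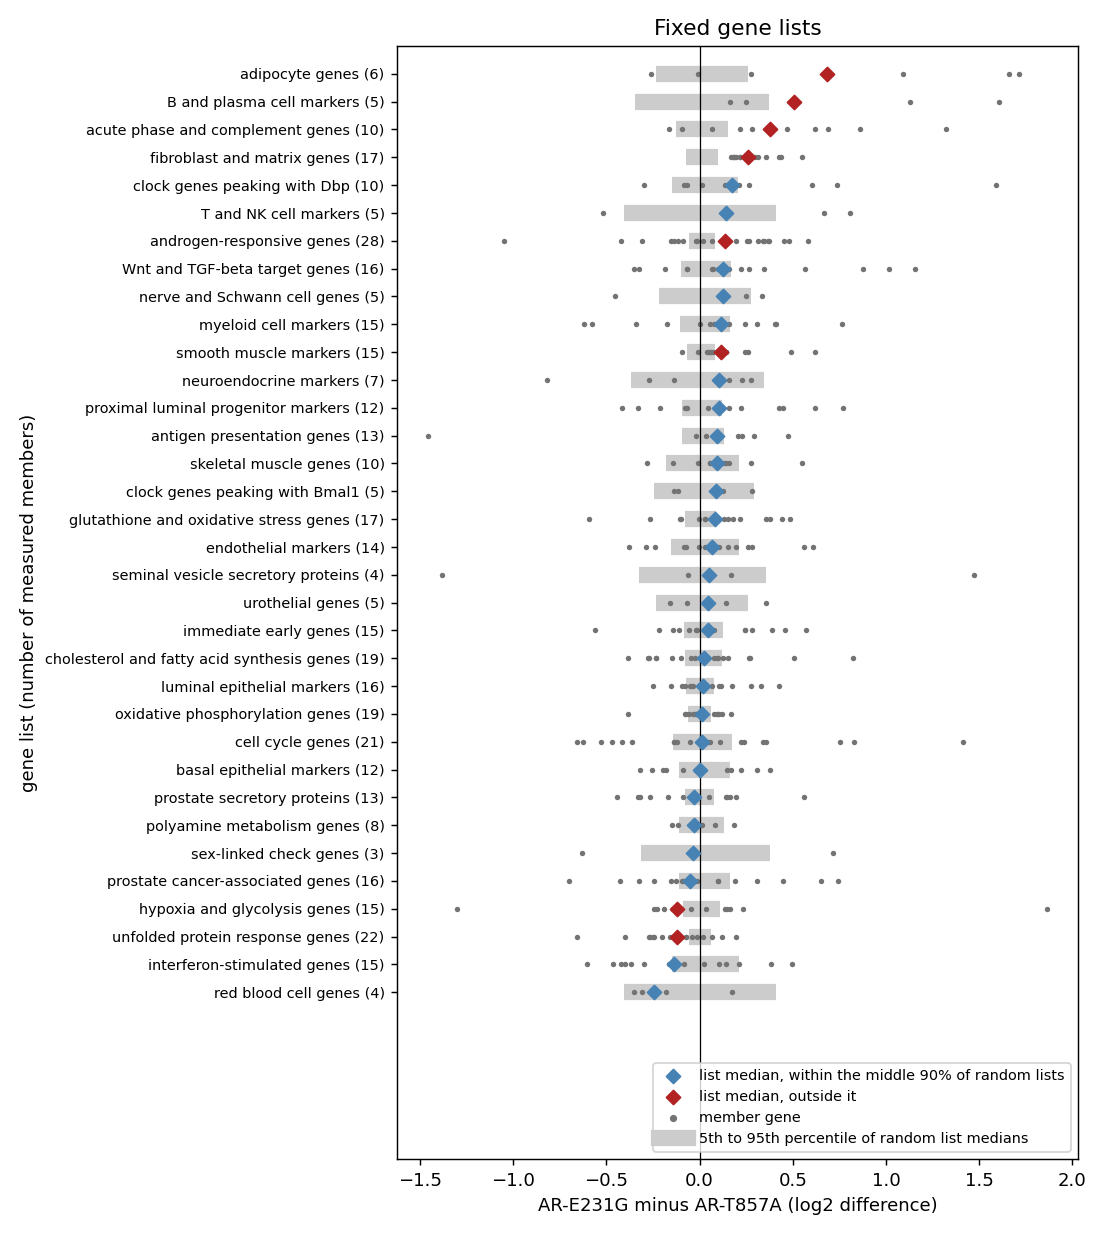
Median log2 difference (AR-E231G minus AR-T857A, 1 array each) of the 34 gene lists as diamonds, member genes as dots and the range of matched random list medians from the 5th to the 95th percentile as grey bars. Lists outside that range are drawn in red, among them fibroblast and matrix genes at 0.26 and unfolded protein response genes at -0.12.

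The RNA integrity controls used, Gapdh and beta-actin, were close on both arrays. The 3' minus 5' log2 value was 0.030 on the AR-E231G array and 0.166 on the AR-T857A array for Gapdh, and 0.391 and 0.357 for beta-actin. The scatter of gene differences depended on brightness, with a robust SD of 0.473 across genes in the dimmest of 4 equal groups and 0.168 in the brightest, and the dimmest group held 15 of the higher and 7 of the lower genes. Of 13 genes past the threshold with further probe sets, 8 had all of them in the same direction and 4 had another one past the threshold. Among the higher of these genes only Cep112 had a probe set in the other direction. Among the lower ones all but Vangl2 had one. Among other list members named, Bhlhe41, Cfb and Nkg7 lay below the filter intensity on the AR-T857A array and Foxa2 and Cenpf on the AR-E231G array. These checks share the RNA pools and say nothing of the spread between animals.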

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

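The tests of the intensity trend, salivary gland tissue, testis tissue and the chromosome segment were chosen only after the result was seen, and the second adipocyte list was chosen after the adipocyte difference but before its own value was known. The control probe sets for dap and trpn, which enter no comparison of the report, each carried a strong signal on only 1 of the 2 arrays. The 6 probe sets for the spiked bacterial transcript dap had a median of 3.59 on the AR-E231G array and 13.7 on the AR-T857A array, a median difference of -9.95. The 3 probe sets for the spiked transcript trpn had medians of 12.5 and 3.43, a median difference of 8.96. The 18 probe sets for the bacterial hybridisation controls, with medians of 9.95 and 9.94, had a median difference of 0.046. The 18 for lys, phe and thr had one of 0.093. Their medians of 3.54 and 3.36 were low on both arrays, so that difference compares dim signal with dim signal.

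The 44 genes past the size threshold were weighed first. For Gapdh and beta-actin, the 3' minus 5' values differed between the arrays by at most -0.136. These 2 controls argued against different RNA degradation, and the other 3' and 5' control pairs were not used. Between the arrays, the 3' and 5' probe sets of the transferrin receptor, with values of 4.60 to 5.55, differed by -0.67 and -0.17. Those of 18S RNA differed by -0.03 and -0.26, and those of pyruvate carboxylase by 0.01 and 0.11. The loess trend of the difference on the mean reached 0.023 in size, against a threshold of 1.5. That test cannot decide on an intensity trend, because RMA equalises the distributions of the arrays and leaves little such trend in any case. Neighbouring tissue in 1 pool stays open, because the highest median of the 4 tissue lists, 0.69 for adipocyte genes, lay between the bounds set in advance. The transgenic lines themselves, the pooled animals and the arrays cannot be told apart with 1 array per line. The dap and trpn signals differed between the arrays, and a difference in processing cannot be told apart from the line either.

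The Klk1b kallikreins on the AR-E231G array were the second pattern. Salivary gland tissue, rich in these kallikreins, would bring its other abundant transcripts, but a list of such genes had a median difference of -0.022 over 16 members and of 0.14 (percentile 90.2) over the 9 past the filter, Amy1 being highest at 1.35 and Car6 next at 0.99, while Smr3a and Bpifa2 measured 2.89 and 3.12 on the AR-E231G array. Testis tissue was argued against in the same way by a median of 0.0053 over 13 Leydig and germ cell genes and of 0.18 (percentile 82.9) over the 7 past the filter, with Prm1 the brightest on the AR-E231G array at 7.15. A difference of the chromosome segment stays open, because 1 of the 20 nearest measured genes outside the family, Klk8, differed by at least 1 in size (-1.09). Without an array of non-transgenic mice, a rise in the AR-E231G line cannot be told apart from a loss in the AR-T857A line. A response of the kallikreins to the mutated receptor of either line may account for the pattern as a hypothesis, untested here. So may the insertion site of a transgene or signal shared between paralogs.

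The adipocyte genes were the third pattern, with Adipoq, Car3 and Pparg higher on the AR-E231G array. Fat tissue in that pool was tested with a second, separate adipocyte list, whose median difference was -0.050. This met the bound set beforehand as counting against fat tissue. The median still decides nothing. Of the 19 measured members, 16 were brighter on the AR-T857A array than Adipoq was on the AR-E231G array (6.06). A small share of fat could therefore be hidden. A difference between the lines stays open too and was not tested.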

How the results depend on the processing

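The filter on the brighter of the 2 arrays was chosen only after the result was seen, and the other settings were planned. No paired analysis was possible because each line had 1 array. The gene counts were 31 higher and 13 lower under loess removal and median centring, with 42 and 44 of the 44 genes shared. Loess moved no value past the filter by more than 0.023, so this setting tests little.

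At 1 log2 unit, 330 probe sets were higher and 314 lower, and 150 genes higher and 100 lower. At 1.5-fold these were 1672, 1529, 762 and 574, so the share of higher genes went from 70.5% to 57.0%. Without the filter 112 probe sets were higher and 103 lower, and 46 genes higher and 26 lower. The filter at the 60th percentile left 25 and 13 probe sets and 16 and 6 genes, all 22 among the 44, because fewer genes were tested. The filter on the brighter array gave 93 and 78 probe sets and 44 higher and 21 lower genes. Averaging probe sets gave 28 higher and 8 lower genes, and 35 of the 44 were shared.

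List medians moved as follows, and the cause was not tested unless fewer members explain it. Without the filter they were 0.23 for B and plasma cell markers, 0.47 for acute phase and complement genes and 0.28 for adipocyte genes. At the 60th percentile they were 0.82 for seminal vesicle proteins, with 2 members, and -0.010, a reversal, for adipocyte genes, with 3. With probe sets averaged they were 0.091 for androgen-responsive, 0.19 for fibroblast and matrix, 0.027 for glutathione and -0.036 for hypoxia genes. Without probe sets shared between transcripts they were -0.035 for luminal, -0.18 for basal, 0.17 for antigen presentation, 0.28 for acute phase, -0.16 for unfolded protein response, 0.22 for Wnt and TGF-beta and 0.97 for adipocyte genes. In that setting the hypoxia list reversed to 0.14 and the gene Smim38 to 0.65. The means of the members were 0.092 for androgen-responsive, 0.025 for antigen presentation, 0.73 for B and plasma cell, 0.0022, a reversal, for hypoxia, 0.24 for Wnt and TGF-beta and 0.31 for Dbp-phase clock genes. Leaving out the largest member gave 0.28 for acute phase, 0.28 for adipocyte and -0.33 for sex-linked genes.

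Of 269 list values under alternatives, 243 moved by less than the spread of matched random list medians (1 SD). The sign changed in 29, of which 3 belonged to lists outside the 5th to 95th percentile and are the reversals named above. The other 26 belonged to lists within that range. Percentiles stayed at 99.56 or more for fibroblast and matrix genes, 99.27 or more for acute phase genes and 0.07 or less for the unfolded protein response in the settings run. Smooth muscle markers went to 94.8 with probe sets averaged. Lists that passed the 95th or 5th percentile in a setting were seminal vesicle proteins (99.2, filter at the 60th), basal markers (2.25, no shared probe sets), glutathione genes (97.7) and sex-linked genes (3.17, largest member out), Dbp-phase clock genes (98.9, mean), interferon-stimulated genes (4.4, probe sets averaged, and 4.95, no filter) and Wnt and TGF-beta targets (98.8, probe sets averaged, 97.6, no shared probe sets, and 98.1, mean). Of 627 values of named genes, 589 moved by less than 0.276, the robust SD between probe sets of a gene. The sign changed in 6, of Smim38, which was past the threshold, and of 5 genes below it: Pias1 (-0.13), Mbp (-0.27) and Mb (0.085) with probe sets averaged, and Vegfa (0.17) and Uty (0.10) without shared probe sets. The 243 and 589 overstate stability, since loess, centring (0.0023) and averaging of 1 probe set could move no value that far. Dim signal limits the calls, as 15 of the 31 higher genes lay in the dimmest of 4 equal groups.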

Other observations

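The estrogen-responsive list was chosen only after the result was seen, and its bounds were set before its own value was known. The genes named next were also chosen after their values were seen. Among higher genes not described in the report were Mmp16, a membrane-anchored matrix metalloproteinase (1.63), and Tnfrsf22, a decoy receptor of the TNF receptor superfamily (1.66). Ndufs5, a subunit of respiratory complex I, was 2.86-fold higher on the AR-E231G array (1.52), whereas the 19 oxidative phosphorylation genes had a median of 0.01. Brinp1, known mainly from neurons, differed by 1.61. The cilium gene Cfap57 differed by 1.57, with 0.46 for its other probe set, and the centrosomal gene Cep112 by 1.62, with -0.17 for its other probe set. Mmp16, Tnfrsf22, Brinp1 and Cep112 lay below the filter intensity of 4.98 on the AR-T857A array.

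A further 26 probe sets past the threshold carried no single gene symbol, 12 of them higher and 14 lower on the AR-E231G array. Their differences reached 5.92 and -3.48, and they were given no gene here.

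Greb1, a known target of the estrogen receptor, was 5.72-fold higher on the AR-E231G array by its brightest probe set. That probe set measured 4.52 on the AR-T857A array, below the filter intensity, and the other Greb1 probe set differed by 0.48. The 5.72-fold value led to the hypothesis that estrogen-responsive genes might be higher together. The median difference of 18 such genes without Greb1 was 0.11, at percentile 90.4 among matched random lists, between the bounds of the 95th and the 75th percentile set beforehand. Of these, 10 were higher and 8 lower, with Cyp1b1 at 0.64 and Rara at -0.61, and their mean lay at percentile 46.8. The hypothesis stays undecided.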
